A study of Homo sapiens with 6 samples.

How the data were processed

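Total RNA of HCT116 cells sorted into a CD133-positive and a CD133-negative fraction was extracted with a column kit, labelled with biotin through a whole-transcript labelling kit and hybridised to Affymetrix arrays, per the labels' protocols. The 6 arrays comprised 3 per fraction, numbered as repetitions 1, 2 and 3 in each. The labels do not say that the repetitions came from separate cultures or sorts, so p-values measure only the spread between these samples, which may be technical.

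The deposited values were log2 signals made by the authors with Robust Multichip Average (RMA), which corrects background, normalizes between arrays and summarises the probes of a probe set, per the labels' design text. The log2 scale was read from the values, which ran from 1.09 to 13.7 with no missing entry. The RMA software version is not given in the sources used here. The design text names a U133 array, whereas the row identifiers and the annotation table are those of a whole-transcript Human Gene ST array, and that annotation was used. Rows for transcripts are probe sets designed to cover the whole transcript, and other rows were taken as controls.

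The table held 32321 rows. Control probe sets were to be recognised by an identifier prefix that this platform lacks. A leading block of 4091 rows, whose identifiers precede the first row with a gene, was left out as controls by a rule set after the table had been seen. Of the 28230 probe sets tested, 19158 carried 1 gene symbol, 1388 carried several and 7684 had none in the annotation. Probe sets with several symbols named no gene. Each of 18404 genes was represented by its probe set of highest mean over the 6 arrays, and 637 genes had more than 1 probe set. No further filter was applied, and 0 columns of the table were left unused. Array medians of the tested probe sets lay between 5.44 and 5.60. The number of arrays limits the precision. A planned comparison of 3' and 5' control probe sets as a measure of RNA quality could not be run, since no such identifiers were present.

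Each comparison was CD133-positive minus CD133-negative, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with group as the only term, and p-values were adjusted by Benjamini-Hochberg over the 28230 probe sets at a threshold of 0.05. This design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The repetition numbers were then checked for pairing. The deviations of same-numbered arrays from their group means correlated at 0.447 to 0.616 across probe sets, above the preset bound of 0.1 in all 3 pairs, and 6 of 6 arrays correlated best with the array of their own number. The numbers therefore paired the arrays by the data, since the labels give no shared day or culture, and the fit with repetition as a block is printed beside results whose call or count it changed.

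The rule for named genes took PROM1 first. It then took, per direction, 12 genes whose groups did not overlap and whose mean in the higher group exceeded the median signal. Those past the threshold came first, ranked by absolute difference, and the places left were filled by the smallest unadjusted p. In each list it took the members that passed, or the 2 with the smallest unadjusted p where none did. A further 6 genes per direction that passed with the block were added after the data were seen, as were single genes said to be so in the text. The value of 1 gene taken by the rule is not reported here.

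The 31 gene lists held 686 entries, of which 624 were measured, after 4 symbols were updated. They covered intestinal stem cell and colorectal tumour-initiating markers, Wnt target genes, pluripotency factors, absorptive colonocyte, goblet and secretory, and enteroendocrine markers, epithelial adhesion genes, mesenchymal transition genes, ABC drug transporters, S phase genes, G2 and mitosis genes, p53 target genes, DNA damage repair genes, mismatch repair genes, hypoxia and glycolysis genes, oxidative phosphorylation genes and cholesterol synthesis genes. They also covered immediate early genes, unfolded protein and amino acid stress genes, heat shock genes, interferon response genes, NF-kappaB and cytokine genes, TGF-beta and BMP response genes, Notch and Hedgehog pathway genes, apoptosis regulators, ribosomal protein genes and histone genes. Leukocyte, fibroblast, endothelial and haematopoietic progenitor, and erythroid markers stood for other cell types. Lists were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists, with an estimated correlation and with fry as alternatives. An exact two-sided permutation test of 3 arrays against 3 cannot give a p below 0.1.

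The fits were tested on simulated data with the 28230 probe sets of this comparison. With group as the only term, 0 of 50 probe sets changed by 0.5 on the log2 scale were recovered, 25 of 50 changed by 1, 47 of 50 changed by 1.5 and 48 of 50 changed by 2, with 0 unchanged probe sets among 120 calls. With the repetition block, 28, 50, 50 and 50 were recovered, with 17 unchanged probe sets among 195 calls. A list shifted by 0.5 was found in both fits, with 0 other lists passing. The simulated noise was drawn independently for each probe set, so this does not test the list calls for genes that vary together. The shift was also larger than any list mean found in the real data.

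The alternatives were the repetition block, each array left out, repeated quantile normalization, centring on array medians, filters on dim probe sets, the mean over a gene's probe sets, an intensity trend with a robust prior, array weights, a minimum change, a looser threshold and a fold threshold without a test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.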

Results

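The series profiled gene expression in HCT116, an established human colorectal carcinoma cell line, after sorting by CD133, a surface glycoprotein used to enrich tumour-initiating cells. The 6 arrays comprised 3 of CD133-positive and 3 of CD133-negative cells. The comparison asked which transcripts differ between the fractions. Signals are RMA values on a log2 scale, and differences are CD133-positive minus CD133-negative.

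Arrays of the same repetition resembled each other more than arrays of the same fraction. Pearson correlations over 28230 probe sets were 0.992 to 0.995 within a repetition and 0.984 to 0.992 within a fraction; these are across probe sets, which are not independent replicates. Repetitions accounted for 64.9% of the variance, fractions for 17.0% and the residual for 18.1%.

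**Figure D1:**
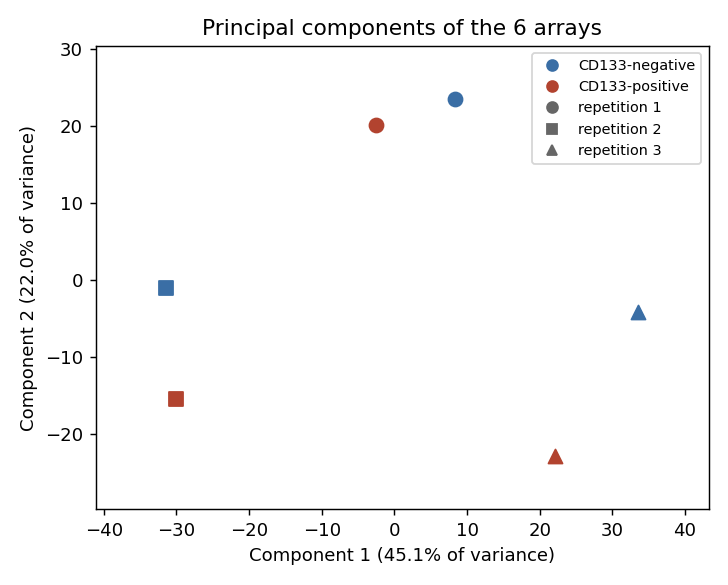
First and second principal components of the 6 arrays over all tested probe sets, with axes in component scores, colour for the sorted fraction and marker shape for the repetition. The first component held 45.1% of the variance and the second 22.0%, and arrays of the same repetition lie near each other.

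PROM1, the gene encoding CD133, had the largest absolute difference of all 18404 genes. Its single probe set (8099476) measured 7.35 ± 0.25 in CD133-positive and 4.57 ± 0.67 in CD133-negative cells (SD, n = 3 each), a log2 difference of 2.77 (SE 0.31), or 6.82-fold. Every CD133-positive array lay at or above 7.09 and every CD133-negative array at or below 5.30. The sort was made on this gene's product, so the difference checks the labels. The limma adjusted p was 0.142 with group as the only term and 0.0120 with the repetition block, and the exact two-sided permutation test gave p = 0.1, the smallest it can give.

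EHF, an epithelial transcription factor of the ETS family, rose in CD133-positive cells and was the only gene to pass with group as the only term. Its probe set (7939314) measured 6.74 ± 0.27 against 4.40 ± 0.20 (SD, n = 3 each), a log2 difference of 2.35 (SE 0.17), or 5.08-fold, with limma adjusted p = 0.0302. It was higher in 3 of 3 repetitions, which the rule for named genes requires, since it takes only genes whose groups do not overlap. The EHF call ended without CD133-negative repetition 1 (adjusted p = 0.181) or 3 (0.184) and without CD133-positive repetition 2 (0.146) or 3 (0.130). It also ended after repeated quantile normalization (0.0865), after centring on array medians (0.0733), against a minimum log2 difference of 0.5 (0.0912) and with the left-out leading block of probe sets included (0.104).

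With group as the only term, 1 of 28230 probe sets passed, against 974 at an unadjusted limma p under 0.05. That is a smaller share than 0.05. This fit leaves the spread between repetitions in its residual, so 0.05 is not the share expected without any difference. The fit with the repetition block had 3202 such probe sets. With the repetition block, 84 probe sets passed, 47 higher and 37 lower, and these represented 36 genes that rose and 32 genes that fell. The groups did not overlap for 7.95% of genes. Chance gives 10% only if all arrays are exchangeable. These arrays were paired by repetition, which makes full separation rarer, so the 10% cannot serve as a reference here. The differences within repetitions all had the same sign for 6645 of 18404 genes, a count that was not tested against chance. With the leading block of probe sets included, 0 probe sets passed in either limma fit, against 1036 at an unadjusted p under 0.05 with group as the only term and 3051 with the repetition block. The 1036 are again a smaller share than 0.05, which is no reference for that fit. Without repetition 3, 0 probe sets passed with limma and the block (2276 at an unadjusted p under 0.05), against 43 without repetition 1 and 18 without repetition 2.

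Of the other genes named by rank as higher in CD133-positive cells, all 11 passed with the repetition block. IL18, an inflammatory cytokine, rose by 1.61 on the log2 scale and CASP4, an inflammatory caspase, by 1.08. ADGRF1, an adhesion G protein-coupled receptor, rose by 1.65, and MACC1, a regulator of MET transcription, by 1.37. SEMA3A, a secreted guidance cue, rose by 1.38. MAL2, a protein of apical transport, rose by 1.05 from a high level of 10.12, and GALNT14, an enzyme of mucin-type glycosylation, by 1.03. MTUS1, a microtubule-associated protein, rose by 0.87, the co-chaperone DNAJC12 by 0.81 and the keratin KRT23 by 0.79.

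Among genes lower in CD133-positive cells, ANGPT2, a ligand of the TEK receptor, fell by 1.72 with the repetition block and TENM3, a teneurin of cell contacts, fell by 1.70. PEG10, an imprinted retrotransposon-derived gene, fell by 1.54, MAP1B, a microtubule-binding protein, fell by 1.41, and the transcription factor GLIS3 fell by 1.40. The RNA-binding protein gene RBM24 fell by 1.19, VIM, encoding the intermediate filament vimentin, fell by 1.05, and PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, fell by 1.00. The matricellular gene CCN1 fell by 1.00, RNF43, a ubiquitin ligase that removes Wnt receptors, fell by 0.95, and the mitochondrial carrier gene UCP2 fell by 0.88. ZNF217, a zinc finger gene, had a difference of -0.77 and passed in neither fit (adjusted p = 0.0688 with the block). The other 22 of these genes beside EHF missed the threshold with group as the only term (adjusted p = 0.142 to 0.258), and their block adjusted p values were 0.0120 to 0.0418.

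**Figure D2:**
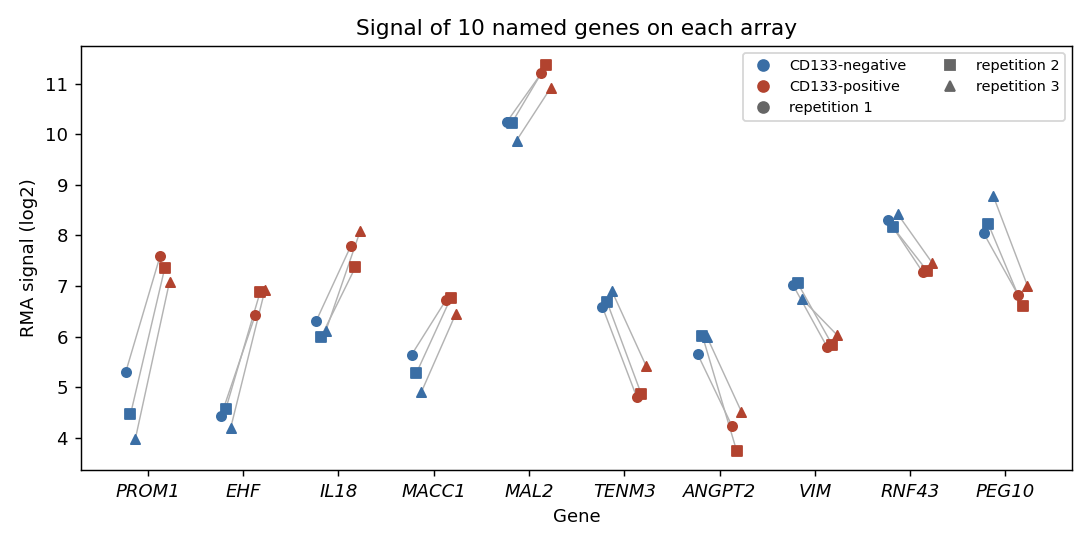
RMA signal (log2, vertical axis) of 10 named genes on each array, with CD133-negative arrays in blue, CD133-positive arrays in red, marker shape for the repetition and grey lines joining arrays of the same repetition. PROM1 had a mean of 7.35 in CD133-positive and 4.57 in CD133-negative cells, and VIM a mean of 5.89 and 6.94.

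Other genes that passed only with the repetition block were chosen after their values were seen. NRIP1, a nuclear receptor corepressor, rose by 2.18 and DPP4, a cell surface peptidase, by 1.44. S100A14, a calcium-binding protein of epithelia, rose by 1.16, the glycosyltransferase gene GALNT5 by 1.01, the lipase gene LIPH by 0.98 and the kinase gene RPS6KA3 by 0.97. The extracellular matrix genes VCAN and FN1 fell by 1.08 and 0.96, and the transcription factor gene KLF12 fell by 1.06. CRIM1, which encodes a BMP-binding membrane protein, fell by 0.86, and PRICKLE1, of planar cell polarity, fell by 0.85. CD24 fell by 1.05, a value that is uncertain because near-identical pseudogene copies share its sequence. The glucose transporter gene SLC2A3 fell by 1.72 and the cell cycle kinase gene CDK6 fell by 1.13.

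Genes of oxidative phosphorylation were higher in CD133-positive cells, 29 of 30 measured members being above 0. The list's median difference was 0.12 and its camera adjusted p was 1.642e-06 (adjusted p = 0.973 with an estimated correlation). Its members with the smallest p were ATP5MC1, an ATP synthase subunit, at 0.53 and NDUFS3, a complex I subunit, at 0.33, and 0 members passed. With the block ATP5MC1 was the 1 member that passed adjusted over the list alone.

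Epithelial adhesion genes were higher, with 17 of 22 members above 0, a median of 0.15 and a camera adjusted p of 0.0227 (adjusted p = 0.985 with an estimated correlation). GRHL2, an epithelial transcription factor, had a difference of 0.49, and the tight junction gene CLDN7 and the trafficking gene RAB25, both chosen after their values were seen, had 0.48 and 0.53. KRT18, an epithelial keratin, went the other way at -0.48, and at -0.38 on a second probe set. With the block these 4 genes passed adjusted over the list alone, and 0 members passed over all probe sets. Within repetitions 1, 2 and 3 the epithelial median was 0.16, 0.18 and 0.05, with 15, 17 and 12 of 22 members higher. The list's mean of 0.12 became 0.07 without CD133-positive repetition 1 and 0.025 without CD133-negative repetition 2. The list's call ended after repeated quantile normalization (adjusted p = 0.121) and with array weights (0.0757, from weights whose estimate did not converge). It also ended without CD133-positive repetition 1 (0.320) and without CD133-negative repetition 2 (0.401). A left-out array unbalances the repetitions. Over both fractions the list's median was 0.12 in repetition 1 and -0.20 in repetition 2 against the others. Leaving out these arrays thus shifts the fit towards 0, so these 2 settings cannot tell a weak difference from that imbalance.

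Mesenchymal transition genes were lower, with 13 of 21 members below 0, a median of -0.08, a mean of -0.24 and a camera adjusted p of 0.0101 (adjusted p = 0.973 with an estimated correlation). Adjusted over the list alone, 5 members passed against 0 over all probe sets. These were VIM, the repressor gene ZEB1 at -0.69, the fibronectin gene FN1 and the matricellular gene CCN2 at -1.31, all lower, and the matrix gene SPARC, higher at 0.68. With the repetition block 3 members fell over all probe sets, namely VIM, FN1 and THBS1, and THBS1, a thrombospondin, fell by 1.31; 7 passed adjusted over the list alone. Within repetitions 1, 2 and 3 the median was -0.09, 0.0011 and -0.016, with 5, 11 and 10 of 21 members higher, and the mean was -0.25, -0.27 and -0.22. The list's call ended without CD133-positive repetition 1 (adjusted p = 0.0798) and without CD133-negative repetition 3 (0.0716). A left-out array unbalances the repetitions. Over both fractions the list's median was -0.07 in repetition 1 and 0.18 in repetition 3 against the others. Leaving out these arrays thus shifts the fit towards 0, so these settings cannot tell a weak difference from that imbalance.

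TGF-beta and BMP response genes were lower, with 15 of 21 members below 0, a median of -0.11 and a camera adjusted p of 0.00508 (adjusted p = 0.973 with an estimated correlation). BAMBI, a decoy receptor, at -0.65 was the 1 member that passed adjusted over the list alone, and the ligand gene BMP4 had a difference of -0.47. With the block 4 members passed adjusted over the list alone, all lower, and 0 over all probe sets. The list's call ended without CD133-positive repetition 2 (adjusted p = 0.107). Over both fractions the list's median was -0.17 in repetition 2 against the others. Leaving out that array unbalances the repetitions and shifts the fit towards 0, so this setting cannot tell a weak difference from that imbalance.

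**Figure D3:**
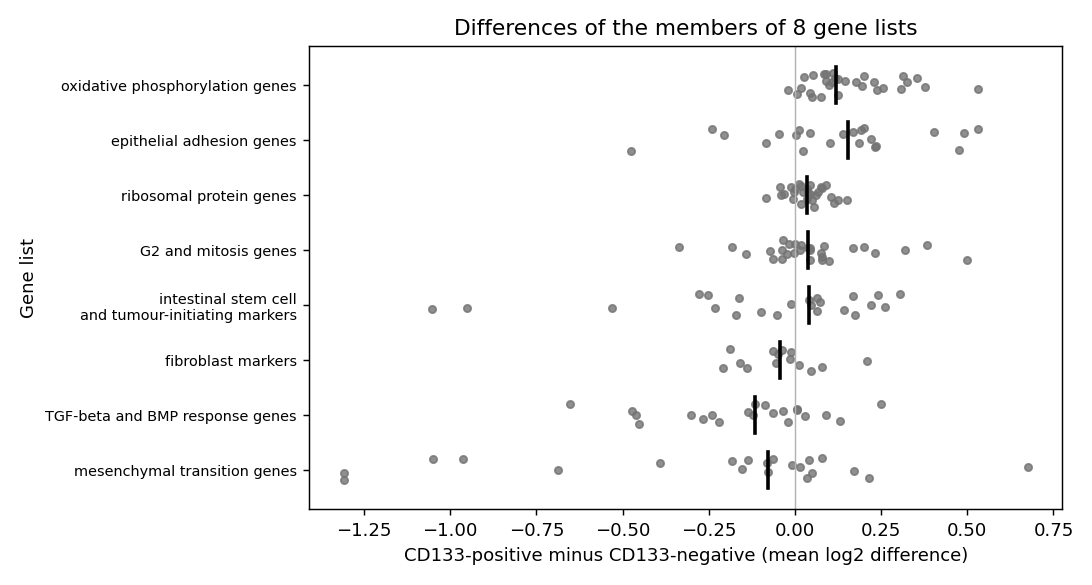
Log2 difference (CD133-positive minus CD133-negative, horizontal axis) of each measured member of 8 gene lists, with a point per gene, scattered vertically for legibility, and a black bar at the list median. The median was 0.12 for oxidative phosphorylation genes and -0.11 for TGF-beta and BMP response genes, and -0.04 for fibroblast markers.

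With the repetition block 7 lists passed camera, the 4 above and 3 others, and 0 passed with an estimated correlation or with limma's fry. Unfolded protein and amino acid stress genes were lower in 19 of 24 members (block adjusted p = 0.00484, against 0.0563 with group as the only term; adjusted p = 0.581 with an estimated correlation). HERPUD1, of endoplasmic reticulum degradation, and the transcription factor gene XBP1 had differences of -0.31 and -0.25, and SLC7A11, a cystine transporter gene, at -0.55 was the 1 member that passed adjusted over the list alone with the block. S phase genes were higher in 21 of 26 members (block adjusted p = 0.0291, against 0.247; adjusted p = 0.850 with an estimated correlation), with MCM3 at 0.24 and E2F1 at -0.13. The S phase median was 0.09 and 0.18 within repetitions 1 and 3 but -0.026 within repetition 2, where 11 of 26 members were higher. Its mean of 0.08 became 0.35 without CD133-negative repetition 2 (camera adjusted p = 3.711e-07) and 0.24 without CD133-positive repetition 3 (0.00140). A left-out array unbalances the repetitions, and S phase genes were higher in repetition 2 (median 0.68) and lower in repetition 3 (-0.55) over both fractions. Wnt target genes were lower in 17 of 24 members (block adjusted p = 0.0415, against 0.0731; adjusted p = 0.581 with an estimated correlation). With the block 5 Wnt targets passed adjusted over the list alone. RNF43, BMP4 at -0.47 and AXIN2 at -0.45 were lower, and ASCL2 at 0.30 and DKK1 at 0.59 were higher, against the direction of the list; with group as the only term RNF43 alone passed so. Wnt target genes also passed camera without CD133-negative repetition 1 (adjusted p = 0.0456) and without CD133-positive repetition 3 (0.0222). The stress list did so without CD133-negative repetition 1 (0.0296) or 3 (0.00175) and without CD133-positive repetition 2 (0.00151). Each of these shifts has the direction that the unbalanced repetitions give, so they are no further support. Over both fractions the Wnt median was -0.02 in repetition 1 and 0.12 in repetition 3 against the others. The stress median was -0.07, 0.19 and -0.15 in repetitions 1, 2 and 3. With group as the only term both lists also passed with filters on dim probe sets, where the Wnt mean of -0.12 became -0.17 with the filter above the median mean (adjusted p = 6.271e-04) and -0.18 with the filter at a signal of 6 (8.533e-04), and the stress list had adjusted p = 0.00840 and 0.00693. The stress list passed too with repeated quantile normalization (0.0254) and with the mean of probe sets (0.0471).

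Intestinal stem cell and colorectal tumour-initiating markers did not shift together, with 12 of 23 members higher and 11 lower (camera adjusted p = 0.705; median 0.04, mean -0.09). RNF43 was the 1 member that passed adjusted over the list alone, and with the block RNF43 and CD24 fell. Pluripotency factors were lower in 5 of 8 members (adjusted p = 0.827), with KLF4 at 0.25 and LIN28A at -0.11, although a second LIN28A probe set had 0.20.

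As lists, markers of intestinal lineages passed camera neither with group as the only term nor with the block. Absorptive colonocyte markers had 11 of 22 members higher (adjusted p = 0.655; median 0.0022, mean -0.03), with the keratin genes KRT18 at -0.48 and KRT8 at -0.24; KRT18 passed adjusted over the list alone with the block. Goblet and secretory markers had 8 of 18 higher (adjusted p = 0.930), with CLCA1 at 0.32 and the defensin gene DEFA6 at 0.17. Enteroendocrine markers had 4 of 15 higher (adjusted p = 0.655); the granin gene SCG2 rose by 0.83 with the block (adjusted p = 0.0336), and the hormone gene PYY had -0.38.

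Markers of other cell types did not pass in these 2 fits either. The camera adjusted p was 0.496 for leukocyte markers, lower in 10 of 15 members, with MS4A1 and LAPTM5 both at -0.28. It was 0.655 for fibroblast markers, lower in 10 of 14, with the collagen gene COL3A1 at -0.21 and TAGLN at 0.21. For endothelial and haematopoietic progenitor markers, lower in 10 of 12, it was 0.270, with CD34 at 0.24 and ENG at -0.23. Erythroid markers had 5 measured members (adjusted p = 0.982; median 0.02, mean -0.01), with AHSP at -0.14 and HBB at 0.09.

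Beyond S phase genes, lists of proliferation and genome maintenance passed camera in neither of the 2 fits. G2 and mitosis genes were higher in 17 of 29 members (adjusted p = 0.555), with CKS2 at 0.38 and CDK1 at 0.50. The calls of 3 of these lists depended on single arrays left out. These fits had group as the only term, so a left-out array unbalances the repetitions. The repetitions differed in these lists over both fractions. In repetition 3 against the others, the median was -0.78 for G2 and mitosis, -0.51 for DNA damage repair and -0.39 for mismatch repair genes. The changes below therefore do not by themselves show a difference between fractions. Without CD133-negative repetition 2, G2 and mitosis, DNA damage repair and mismatch repair genes were higher (adjusted p = 0.00259, 0.00407 and 0.00758), and likewise without CD133-positive repetition 3 (8.276e-04, 0.00596 and 0.0222). G2 and mitosis genes were also higher without CD133-negative repetition 1 (0.0178). Without CD133-negative repetition 3, G2 and mitosis genes and DNA damage repair genes were lower, at means of -0.27 and -0.13 (adjusted p = 2.792e-07 and 0.0176). p53 target genes were higher in 17 of 25 (adjusted p = 0.270); GDF15, a stress-responsive cytokine gene, rose by 0.71 with the block (adjusted p = 0.0413), and PMAIP1 had 0.38. DNA damage repair genes were higher in 14 of 23 (adjusted p = 0.689), with ATM at -0.33 and CHEK2 at 0.33, and mismatch repair genes in 7 of 8 (adjusted p = 0.356), with MLH3 at 0.37 and MSH3 at -0.11. MLH3 and the helicase gene BLM at 0.60 passed adjusted over their own list alone with the block. Apoptosis regulators were higher in 10 of 24 (adjusted p = 0.859), with PMAIP1 at 0.38 and BIRC2 at -0.29; PMAIP1 and APAF1, at -0.46, passed adjusted over the list alone with the block. Histone genes, whose near-identical copies make single values uncertain, were higher in 10 of 15 (adjusted p = 0.203), with H2BC8 at 0.29 and H2BC12 at -0.45.

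Metabolic and stress lists beyond those above passed camera in neither of the 2 fits. Hypoxia and glycolysis genes were higher in 15 of 28 members (adjusted p = 0.859; median 0.01, mean -0.03), with the glucose transporter gene SLC2A1 at -0.75 and VEGFA at -0.28; SLC2A1 passed adjusted over the list alone with the block. The hypoxia list was higher without CD133-positive repetition 2 (mean 0.28, camera adjusted p = 0.00218) and lower without CD133-negative repetition 2 (mean -0.36, camera adjusted p = 8.935e-04). Over both fractions this list was lower in repetition 2 (median -0.69 against the others), so leaving out either array of it shifts the fit in these directions. Cholesterol synthesis genes were higher in 7 of 18 (adjusted p = 0.675), with HMGCS1 at -0.46 and MVK at 0.19. They passed, as lower, without CD133-negative repetition 2 (0.0469). Over both fractions this list was lower in repetition 2 (median -0.30 against the others), so leaving out that array shifts the fit in this direction. ABC drug transporters were higher in 4 of 13 (adjusted p = 0.827), with ABCC5 at -0.23 and ABCC2 at 0.44, the latter passing adjusted over the list alone with the block. Heat shock genes were higher in 7 of 12 (adjusted p = 0.705), with HSPB1 at 0.12 and HSPH1 at -0.21, and ribosomal protein genes in 20 of 28 (adjusted p = 0.203), with RPS25 at 0.11 and RPL38 at 0.15. The ribosomal list passed without CD133-positive repetition 2 (0.0478) and without CD133-negative repetition 3 (0.0288). Over both fractions its median was -0.08 in repetition 2 and 0.13 in repetition 3 against the others. Both shifts thus have the direction that the unbalanced repetitions give.

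Signalling lists outside TGF-beta and Wnt passed camera in neither of the 2 fits. Notch and Hedgehog pathway genes were lower in 17 of 22 members (adjusted p = 0.0731), with the Notch targets HES1 at -0.34 and HEY2 at -0.35; they passed without CD133-negative repetition 2 (0.0102) and without CD133-positive repetition 3 (0.00820). Immediate early genes were lower in 17 of 25 (adjusted p = 0.227); CCN1 was the 1 member that passed adjusted over the list alone, and HES1 had -0.34. Immediate early genes passed without CD133-positive repetition 1 (0.00693) and without CD133-negative repetition 2 (0.0303). Interferon response genes were higher in 16 of 32 (adjusted p = 0.140), with the immunoproteasome gene PSMB9 at 0.61 and IFIT2 at 0.40, and passed without CD133-positive repetition 2 (0.00809) and without CD133-negative repetition 3 (0.0176). PSMB9, IFIT2 and USP18, at 0.45, passed adjusted over the list alone with the block. The passes of the Notch, immediate early and interferon lists with an array left out have the direction that the unbalanced repetitions give. Over both fractions their medians in repetition 2 against the others were -0.13, -0.07 and -0.12. In repetition 3 the Notch and interferon medians were 0.10 and 0.14, and in repetition 1 the immediate early median was 0.22. NF-kappaB and cytokine genes were lower in 15 of 22 (adjusted p = 0.359), with the adhesion gene ICAM1 at -0.86 and LIF at 0.48, both passing adjusted over the list alone with the block. With group as the only term, members passed adjusted over the list alone in 5 of the 31 lists and over all probe sets in 0. With the repetition block they did so in 18 and in 6 lists. AXIN2, ASCL2, DKK1, SLC7A11, BLM, APAF1, USP18, CCN2, SPARC and THBS1, like the genes CDK6 and SLC2A3, were named after their values were seen.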

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

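The alternatives in which all left-out probe sets were restored, those restricted to probe sets with 1 gene, and those that vary the fit with the repetition block or leave out a whole repetition from it were chosen after seeing the data. With group as the only term, 1 probe set passed. The count was 84 with the replicate block, 33 with array weights, 66 at a log2 difference of 1 or more without a test, and 0 with repeated quantile normalization, median centring, limma treat or all probe sets included; leaving out single arrays gave 0 to 2. At an unadjusted p under 0.05 the counts were 1102 with quantile normalization, 906 with centring and 75 with treat. These are also smaller shares of the probe sets than 0.05, which is no reference with group as the only term. The treat p also tests a minimum log2 difference of 0.5. Genes that rose numbered 36, 15 and 24 in the first 3 of these settings and 0 in the others, with 0 to 1 over single arrays left out, and genes that fell numbered 32, 11 and 18. Lists passing camera went from 4 to 7 with the block, with a filter at a log2 signal of 6, with array weights and at an adjusted p under 0.1, to 0 with an estimated correlation or fry, and to 3 to 11 over single arrays left out. PROM1 passed with the block (2.77, adjusted p = 0.0120) and with array weights (2.25, adjusted p = 0.0463). EHF had a log2 difference of at least 2.23, with adjusted p from 0.00441 to 0.184, and passed in 9 of 17 alternatives. In the fit with the replicate block, a filter on probe sets above the median mean gave 403 probe sets (168 genes higher, 145 lower), a filter at a signal of 6 gave 479 (190, 181), an intensity trend with a robust prior 389 (147, 150), an adjusted p under 0.1 gave 226 (95, 77), and only probe sets with 1 gene 216 (116, 96). It gave 0 (0, 0) with treat (148 at an unadjusted p under 0.05) or with all probe sets, and 0 to 43 without a repetition (0 to 19, 0 to 13). The 7 lists of that fit became 0 with an estimated correlation or fry and 4 to 7 without a repetition. Why the counts moved was not tested in any setting. A left-out array also unbalances the repetitions, and with group as the only term a difference between repetitions then enters the difference between fractions. Such differences were large for some lists. The median was -0.69 in repetition 2 against the others for hypoxia and glycolysis genes. In repetition 3 it was -0.78 for G2 and mitosis genes and -0.51 for DNA damage repair genes. Of the 24 ranked genes, 22 passed with the block and missed the threshold without it, 17 did so with array weights, and 0 of 404 values changed sign. The steady sign is no support, because the rule took only genes whose groups did not overlap, which fixes the sign in most settings. The mean deviation correlation of paired arrays, 0.551, became 0.739 above the median mean. Among named genes, signs turned for values that passed in no setting: with array weights HBB to -0.052, TAGLN to -0.0029 and MSH3 to 0.017, and with the mean of its probe sets LIN28A to 0.043. Over single arrays left out, HBB ran from -0.030 to 0.16, HSPH1 from -0.43 to 0.0010 and MSH3 from -0.20 to 0.037. The list mean ran from -0.27 to 0.26 for G2 and mitosis genes, from -0.13 to 0.22 for DNA damage repair genes and from -0.36 to 0.28 for hypoxia and glycolysis genes. The lower end for G2 and mitosis and for repair came without CD133-negative repetition 3, and the upper end for hypoxia without CD133-positive repetition 2. These 3 values have the sign opposite to the list mean over all 6 arrays and passed camera (adjusted p = 2.792e-07, 0.0176 and 0.00218). Each has the direction that the unbalanced repetitions give, so they are not evidence of a difference between the fractions. With array weights the hypoxia, immediate early, Notch and Hedgehog and S phase lists passed, but for lists the estimate of these weights stopped before it converged, so its list values are uncertain. Absorptive colonocyte markers passed camera with the filter at a signal of 6 (adjusted p = 0.0496), where their mean of -0.03 became -0.12. The alternative that leaves out probe sets with cross-hybridising suffixes was not run, because this platform has no such identifiers. Signal over background could not be judged from RMA values, which limits what can be said of dim genes.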

Other observations

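The tests of fibroblast RNA and of copy number below were chosen only after the results they bear on were seen. The repetitions differed from each other in cell cycle and hypoxia genes, over both fractions. With limma's F-test 2817 genes differed between repetitions. Each repetition held 1 array of each fraction, and the tests between repetitions treat these 2 paired arrays as replicates. Their p-values therefore do not measure a spread between separate cultures. G2 and mitosis genes were lower in repetition 3 than in the others, 29 of 29 members, with a median of -0.78 (camera adjusted p = 8.786e-20; adjusted p = 0.537 with an estimated correlation). S phase genes were higher in repetition 2 in 26 of 26 members, with a median of 0.68, and lower in repetition 3, with a median of -0.55 (adjusted p = 1.647e-16 and 4.295e-14; adjusted p = 0.537 with an estimated correlation for both). Hypoxia and glycolysis genes were lower in repetition 2 in 27 of 28 members, with a median of -0.69, and higher in repetition 1, with a median of 0.37 (adjusted p = 8.196e-17 and 2.362e-22; adjusted p = 0.537 with an estimated correlation for both). The hypoxia list was also higher in repetition 3 in 24 of 28 members, with a median of 0.33 (camera adjusted p = 6.348e-07, or 0.537 with an estimated correlation). The glycolytic genes ENO2 and ALDOC had levels of 8.46 and 8.47 in repetition 2, against 10.49 and 10.70 in repetition 1, and the hypoxia gene NDRG1 had 8.58 against 10.65. Cholesterol synthesis genes were higher in repetition 3 in 17 of 18 members, with a median of 0.36, and lower in repetition 2 in 17 of 18, with a median of -0.30. The camera adjusted p values were 1.445e-05 and 2.370e-05, and 0.537 for both with an estimated correlation.

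Unequal value distributions of the arrays were tested for the G2 and mitosis genes of repetition 3 alone. After quantile normalization the G2 and mitosis genes still lay at a median of -0.65 in repetition 3 (SE over members 0.05), which argues against that explanation for these genes; it was not tested for the S phase, hypoxia and cholesterol genes. Culture density, passage or timing may differ between repetitions and stays open, since the labels record none of these. No biological explanation was tested, because the design names no group by repetition.

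The higher oxidative phosphorylation genes in CD133-positive cells were set against a shift that depends on signal level. The list's median exceeded 99.99% of 10000 random lists matched on mean signal, whose upper bound was 0.07, which argues against that shift. The medians within repetitions 1, 2 and 3 were 0.072, 0.097 and 0.215, all above 0, so no single repetition decided the direction. Repetition 3 had the largest difference. The SE over members was 0.022 for the lowest, which measures the spread of genes on 1 pair of arrays and not between repetitions. Correlation among the members stays open, because the list lost its call with an estimated correlation (adjusted p = 0.973). A higher respiratory gene level in CD133-positive cells is therefore a hypothesis, which may be followed up with independent sorts.

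The lower mesenchymal transition genes were set against fibroblast RNA in the CD133-negative fraction, which a culture of a cell line should lack. Fibroblast markers had a median of only -0.043 (SE over members 0.030), and the collagen gene COL3A1 had levels of 5.12 and 5.33, so that explanation is not borne out. The list's mean lay below all 10000 matched lists (percentile 0; lower bound -0.08), against a shift with signal level, although its median of -0.08 shows that a few members carry it. A candidate explanation is lower output of YAP and TEAD, since CCN1, CCN2 and THBS1 are known targets. A list of 22 target genes was written from memory after those genes were seen, and tested on the 17 members whose values had not been seen. Its membership could not be checked against a published source, and the values below rest on it.

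Of these 17 genes 13 were lower in CD133-positive cells, and their median of -0.13 lay at percentile 0.04 of matched lists, in the predicted direction. The largest decreases were ASAP1 at -0.80, ANKRD1 at -0.64 and AMOTL2 at -0.52; 0 of the 17 passed with the repetition block. The camera p was 5.852e-04, and with an estimated correlation it was 0.0321, or 0.0516 with the block; these are unadjusted. Of the 10 splits of the arrays 2 gave a median as large in size, the real one included, and the highest other, 0.22, came from a split that mixes repetitions. Among the 4 splits that part all pairs the highest other was 0.07, and 4 splits are too few for a share under 0.05. Another of these 4 splits also put 13 of the 17 genes on the same side, so that count does not set the real grouping apart. The matched lists do not keep the correlation among members. The median has the direction that lower YAP and TEAD output would give, which remains a hypothesis.

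Copy-number segments of a subclone were tested as a source of the genes that passed with the repetition block. Over 10705 runs of 25 neighbouring expressed genes, in the gene order of GRCh38.p14, the largest median difference in size was 0.158, in the run from ZBTB11-AS1 to USF3, under the bound of 0.3. Runs with a median of 0.3 or more were thus not seen. The test did not look at where the genes that passed lie, so it cannot tell whether some are neighbours. Smaller segments, and segments carried by only some cells of a fraction, stay open. Differences of neighbouring genes correlated weakly across genes, which are not independent replicates (Pearson r = 0.0702, Spearman rho = 0.0555). The permutation p was 1.000e-05, the smallest that 100000 permutations can give, so an effect of position on some genes stays open.

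Other splits of the 6 arrays into 3 and 3 bear on the counts, but 10 splits, or 4 that part all pairs, are too few for a share under 0.05. With group as the only term, 2 of 10 splits gave as many probe sets as the real 1 (highest other 1), 1 of 10 as many genes (real 1, highest other 0) and 7 of 10 as many lists (real 4, highest other 13). The 6 splits that gave more lists all mix repetitions, which points to the structure of repetitions in the samples. With the block, 1 of 4 splits gave as many probe sets (real 84, highest other 0), 1 of 4 as many genes (real 68, highest other 0) and 1 of 4 as many lists (real 7, highest other 5).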
